A study of Mus musculus with 10 samples.

How the data were processed

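Total RNA from lungs of 10 female C57BL/6 mice was extracted with Trizol, cleaned on Qiagen columns, labelled with biotin and hybridised to Affymetrix Mouse430_2 arrays, 1 animal per array, per the labels' protocols. The deposited table holds 1 log2 value for each of 45101 probe sets on each array. GCRMA, which corrects the background with the probes' sequence, normalizes between arrays and summarises the probes of a set, is named in the submitters' processing notes. Its version and any filter are not given in the sources used here. That the deposited values are log2 and not centred per gene was read from their range, 0.619 to 16.3, and from the nearly equal quartiles of the arrays. Scanner files were not used here, so detection calls and scan dates were not analysed here. GCRMA compresses dim probe sets towards a common floor, which makes fold changes of dim genes too small.

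Groups were taken from the titles, which give the dose as 50 or 0 ppm. The field on treatment of control replicate 4 names a control but gives no dose. Labels disagree on the compound: the series names arsenate and the sample protocols arsenite. The titles of all arsenic samples carry 20 as their first number and those of all controls carry 4; its meaning is not given, and if it marks a cage or a batch, that cannot be told apart from the exposure. The labels give each animal a number of its own, so the replicates are separate animals.

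Probe sets were named through the platform annotation provided, in which 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Of the array's 64 control probe sets, 51 were not listed and 13 had 1 gene symbol. Symbols were compared with RefSeq through Entrez identifiers, which changed 0 of them. Probe sets with several symbols or none named no gene. A probe set was kept if its value exceeded the median of the whole table, 4.20, on at least 5 arrays; 22552 passed, of which 19501 had 1 symbol. Each gene was represented by its kept probe set with the highest mean over the 10 arrays, which gave 11333 genes. Control probe sets stood for 2 of these, Actb and Gapdh, the latter a member of the hypoxia and glycolysis list; without them the same 10 lists passed, hypoxia at an adjusted p of 0.00885.

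The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method; an adjusted p under 0.05 counted as past the threshold. The empirical Bayes step had 2.82 prior degrees of freedom. Before the data were examined, 64 gene lists of pathways, cell types and controls were fixed, of which 57 had at least 4 genes tested. They were tested with camera at its preset correlation of 0.01, and again with camera's estimated correlation and with fry. Single values per animal were compared by exact permutation tests over all 252 splits. Figures were drawn with matplotlib 3.10.9.

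The genes named in the text followed a rule also fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap (11 falls qualified), up to 4 members with the smallest p from each list described, and 19 genes of arsenic response, lung identity, the clock and xenobiotic metabolism whatever their values. Other genes are said to have been named after their values were seen.

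On simulated data with the spread of the 11333 genes of the arsenic comparison, limma called 34 of 67 genes changed by 0.5 log2, 61 of 67 changed by 1 and 66 of 66 changed by 2, and 10 of 11133 unchanged genes. Camera called 5 of 5 lists shifted by 0.5 and 0 of 46 lists without a shifted gene. The simulated genes were independent of each other, so this does not give camera's error rate for lists whose members move together. In other splits of the real arrays camera called a median of 13 lists.

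Alternatives were other filters, other rules for probe sets, quantile normalization, median centring, trended and robust eBayes, array weights, a replicate block, a t-test with equal variances, other thresholds and leaving out each array. Alternatives chosen after seeing the data were the kidney level, the Actb 3' to 5' ratio and another split of the arrays as covariates, leaving out arsenic animal 4 and control animal 2 together, leaving out the control probe sets, and taking the repressor genes Cry1 and Nfil3 out of the positive clock list. The kidney level is the mean log2 value of 26 kidney transcripts, of which 12 had been seen along the third principal component.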

Results

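Gene expression was measured in whole lungs of 10 adult female C57BL/6 mice, an inbred laboratory strain. 5 mice had arsenic at 50 ppm in their drinking water for 12 weeks, starting at 8 weeks of age, and 5 control mice had deionized water. Each animal gave 1 Affymetrix oligonucleotide array, which reads every transcript with 1 or more probe sets. The series as a whole names the compound as arsenate, whereas the field on treatment of each sample names arsenite, so the treated group is called arsenic here. The comparison asks which transcripts of the lung differ after subchronic arsenic exposure. All 10 arrays had close distributions, with medians between 4.11 and 4.26 on the log2 scale, and correlated with each other over probe sets at 0.990 to 0.997. The number of arrays limits the precision of every value below.

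In arsenic-exposed lungs, 4 of the 16 measured genes fixed beforehand as targets of glucocorticoid hormone rose. Of the 21 measured genes fixed as immediate-early genes, 4 fell. The largest rise was that of Zbtb16, a zinc-finger transcription factor, from 8.03 ± 0.65 to 10.39 ± 0.23 (log2, mean ± SD, n = 5 each), or 5.15-fold. Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, rose 3.39-fold, from 8.16 ± 0.38 to 9.92 ± 0.34. The largest falls were those of the orphan nuclear receptor Nr4a1, from 11.95 ± 0.53 to 9.41 ± 0.29 (5.80-fold), and of the zinc-finger factor Egr3, from 8.79 ± 0.70 to 6.26 ± 0.64 (5.76-fold). Of these 8 genes, Zbtb16, Fkbp5 and Nr4a1 passed in all 10 fits that left out 1 array, Egr3 in 6, Cdkn1a in 2, Sult1a1 in 1 and Klf2 and Klf4 in 0 (limma adjusted p up to 0.143). Without a filter on dim probe sets the calls of Egr3 (adjusted p = 0.0685), Klf4 (0.0734), Cdkn1a (0.0850), Sult1a1 (0.0856) and Klf2 (0.107) ended. The classical arsenic-responsive genes Hmox1, Mt1 and Mt2 did not pass the test.

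**Figure D1:**
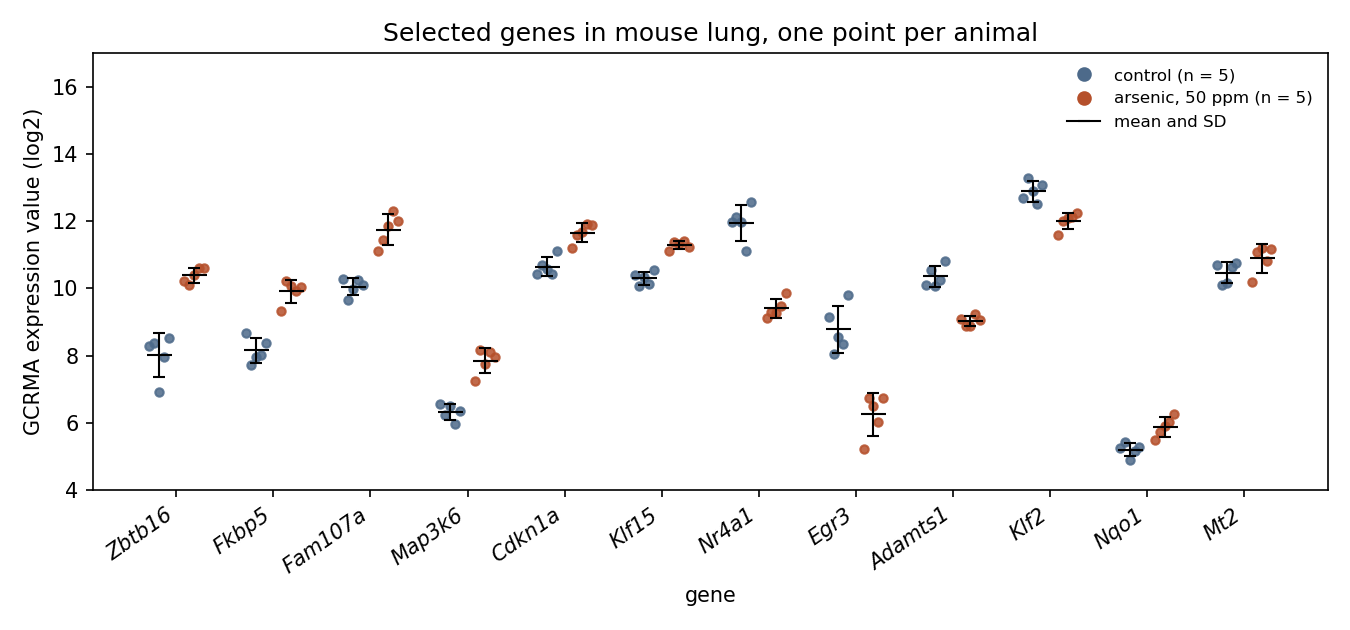
Expression value (log2, vertical axis) of 12 genes (horizontal axis) in lungs of control and arsenic-exposed mice; each point is 1 animal, and black marks give the mean and SD of 5 animals. The 5 arsenic values of Zbtb16 and Fkbp5 all lie above the 5 control values and those of Nr4a1 and Egr3 all below them, whereas the groups overlap for Mt2.

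With limma and Benjamini-Hochberg adjustment, 54 of 11333 genes passed an adjusted p of 0.05, 43 of them higher and 11 lower with arsenic. With each probe set tested on its own, 99 of 22495 passed, 59 higher and 40 lower, and without a filter 19 genes, 16 higher and 3 lower. At an unadjusted p of 0.05 there were 1778 genes, against 567 expected by chance. The 54 genes changed by a median of 1.69-fold, and 15 of them by at least 2-fold. In all 54 the 5 arsenic values lay entirely above or entirely below the 5 control values. Over all tested genes this held for 411, or 3.63%, where chance gives 0.794%. Of the 54 genes, 21 had another probe set past the filter, which in each of the 21 had the same sign and an unadjusted limma p under 0.05.

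Further rises were led by Fam107a, an actin-associated protein induced by stress, with a log2 fold change of 1.69 (SE 0.21, adjusted p = 0.00849), and by the kinase Map3k6, with 1.52 (SE 0.18, adjusted p = 0.00629). Fst, which encodes the activin-binding protein follistatin, rose by 1.26, the laforin-binding ubiquitin ligase gene Nhlrc1 by 1.25, Sema7a by 1.23, the metalloprotease gene Adamts15 by 1.11, Spsb1 by 1.03 and the Notch target Hey1 by 1.00 on the log2 scale. Klf15, a Krüppel-like factor of metabolic control, rose by 0.99 (SE 0.10, adjusted p = 0.00629). Among the falls, the metalloprotease gene Adamts1 had a log2 fold change of -1.33 (SE 0.15, adjusted p = 0.00629) and Ccdc25 of -1.29. Slc25a25, a mitochondrial carrier of adenine nucleotides, had -0.97, Zfp462 -0.77, Rsrp1 -0.61, Nipal1 -0.61 and Eva1a -0.42. The calls of Fst (limma adjusted p = 0.117), Sema7a (0.0983), Adamts15 (0.0548), Spsb1 (0.0537) and Ccdc25 (0.0773) ended without a filter on dim probe sets. So did those of Slc25a25 (0.108), Zfp462 (0.0850), Rsrp1 (0.0765) and Nipal1 (0.0940), while those of the other genes of this paragraph held.

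Of the 16 measured glucocorticoid targets, 4 rose, none fell and 12 did not pass over all genes; adjusted over the list alone, 5 rose and 1 fell. Those that rose were Zbtb16, Fkbp5, the cyclin-dependent kinase inhibitor Cdkn1a, from 10.65 ± 0.28 to 11.66 ± 0.28, and the sulfotransferase Sult1a1, from 11.50 ± 0.28 to 12.34 ± 0.19. The list as a whole lay higher than other genes (camera adjusted p = 0.00167), but not past the threshold when its members' correlation was estimated (adjusted p = 0.848 with an estimated correlation). Its mean log2 difference was 0.52 and its median 0.33. With the mean level of kidney transcripts as a covariate, chosen after seeing the data, the mean difference was 0.49 and the camera adjusted p 0.105. Without arsenic animal 4 and control animal 2, also chosen after seeing the data, the mean difference was 0.43 and the camera adjusted p 0.153.

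Of 21 measured immediate-early genes, which are induced within minutes by growth factors, calcium or stress, 4 fell, none rose and 17 did not pass. Adjusted over the list alone, 10 fell and 1 rose. Nr4a1 and Egr3 were joined by the Krüppel-like factors Klf2 (log2 fold change -0.88, SE 0.16) and Klf4 (-0.55, SE 0.10). The list had a mean difference of -0.55 and a median of -0.23 (camera adjusted p = 1.96e-08; adjusted p = 0.618 with an estimated correlation). The phosphatase gene Dusp1, which both lists hold, had a log2 fold change of -0.69 (adjusted p = 0.195) and was named after its value was seen.

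**Figure D2:**
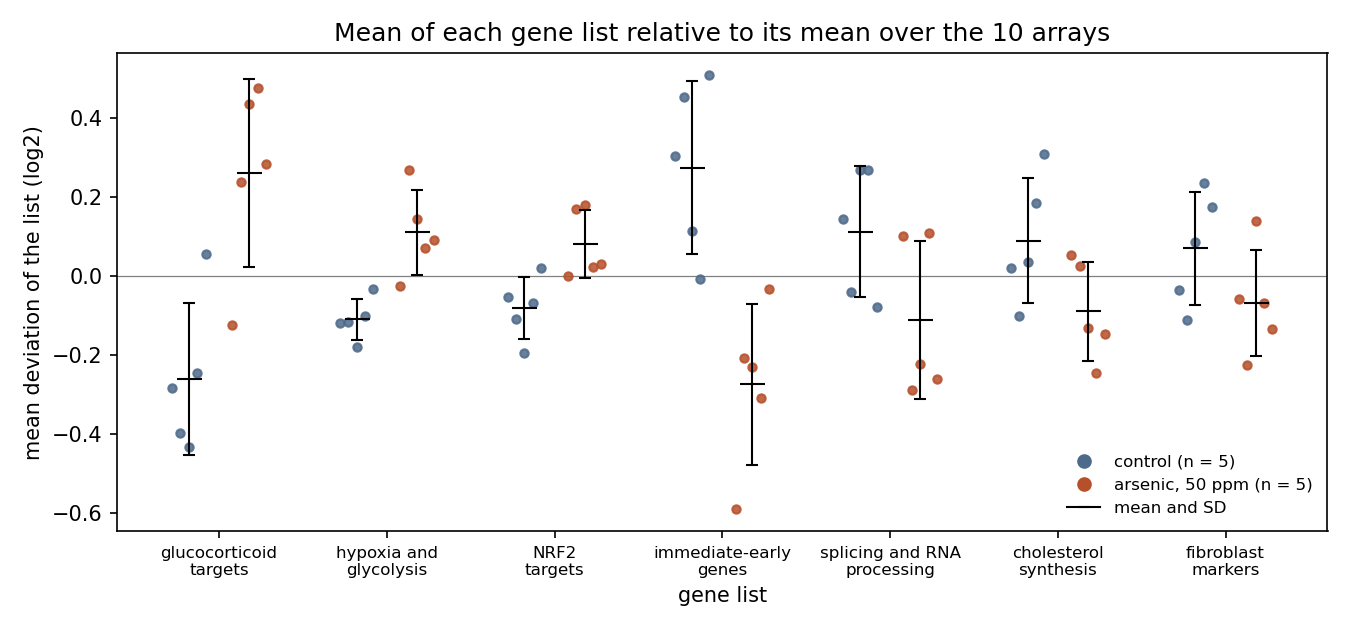
Mean deviation of 7 gene lists (horizontal axis) from their mean over the 10 arrays (log2, vertical axis); each point is 1 animal, and black marks give the mean and SD of 5 animals. Immediate-early genes lie lower with arsenic by 0.55 without overlap, and the hypoxia groups also part; glucocorticoid targets lie higher by 0.52, but control replicate 5 (0.055) lies above arsenic replicate 1 (-0.13), and the groups overlap for the other lists too.

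A pair of metabolic and protective lists lay higher. Of 18 hypoxia and glycolysis genes, 1 rose over all genes and 4 adjusted over the list alone. The gene that rose over all genes was Adm, encoding the vasodilator adrenomedullin, from 7.57 ± 0.25 to 8.36 ± 0.14. Adm passed in 3 of the 10 fits that left out 1 array, and its call ended without a filter on dim probe sets (limma adjusted p = 0.0564). Hexokinase 2 (Hk2) had a log2 fold change of 0.66 (adjusted p = 0.0991), Ndrg1 of 0.54 and the mitophagy receptor Bnip3 of 0.41, all without passing over all genes. The list's camera adjusted p was 0.0176 (adjusted p = 0.848 with an estimated correlation), 0.0546 with quantile normalization and 0.0577 without control replicate 2. Of 26 targets of the oxidative-stress factor NRF2, none passed over all genes and 1 rose adjusted over the list alone. This was the quinone reductase Nqo1, at 5.21 ± 0.19 in controls and 5.89 ± 0.29 with arsenic (adjusted p over all genes 0.0888). The glutathione transferases Gsta2, Gstm1 and Gsta3 had log2 fold changes of 0.62, 0.27 and 0.32. Of the 26 members 23 had a positive difference, as had 63.2% of all genes tested, whose median log2 difference was 0.057, and the list's camera adjusted p was 0.0485 (adjusted p = 0.848 with an estimated correlation), 0.103 with quantile normalization and 0.0507 with arrays centred on their median.

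The remaining lists past the camera threshold lay lower, with no member past the threshold over all genes. Splicing and RNA-processing genes (28 measured) had a mean difference of -0.22, and of -0.37 with the kidney level as a covariate, with Clk1 at -0.82, Luc7l3 at -0.77, the nuclear RNA Malat1 at -0.55 and Rbm25 at -0.48 (camera adjusted p = 3.16e-06; adjusted p = 0.848 with an estimated correlation). Of 19 genes of cholesterol synthesis, 16 had a negative difference; adjusted over the list alone, 2 fell and 1 rose. These were the sterol carrier Stard4 (-0.58, SE 0.12), the synthase Hmgcs1 (-0.68, SE 0.17) and, upward, the kinase Pmvk (0.50, SE 0.15), while Insig1 had -0.27. The list's camera adjusted p was 0.00028 (adjusted p = 0.848 with an estimated correlation).

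Fibroblast markers (17 measured) had a mean difference of -0.14 (-0.083 with array weights), and 1 of them, the collagen gene Col3a1 (-0.39, SE 0.08), fell adjusted over the list alone. Col1a2 had -0.28, Col1a1 -0.24 and Clec3b -0.23 (without control replicate 5, -0.15 and -0.14), and the list's camera adjusted p was 0.00335 (adjusted p = 0.618 with an estimated correlation). The extracellular matrix list, which shares collagens with the fibroblast list, had a mean of -0.07 and a median of -0.03 over 27 genes, with Col6a2 at -0.31 and Loxl1 at -0.34 (camera adjusted p = 0.0494; adjusted p = 0.848 with an estimated correlation). A second probe set of Loxl1 had the opposite sign, 0.08. All 9 genes of antigen presentation on MHC class II had a negative difference, with H2-Ob at -0.60, H2-Ab1 at -0.28, Cd74 at -0.21 and H2-Aa at -0.15 (without control replicate 2, H2-Ab1 at -0.18 and Cd74 at -0.14; camera adjusted p = 0.0103; adjusted p = 0.848 with an estimated correlation). With the kidney level as a covariate the mean of this list went from -0.23 to -0.036 and its camera adjusted p was 0.586. B-cell markers (15 measured), among them Ebf1 at -0.49, Fcer2a at -0.61, Ms4a1 at -0.41 and Spib at -0.26, gave a camera adjusted p of 0.0333 (adjusted p = 0.848 with an estimated correlation). Single animals moved Ms4a1 to -0.21, -0.63 and -0.27 (without control replicates 1 and 5 and arsenic replicate 2) and Spib to -0.12, -0.076, -0.46 and -0.42 (without control replicates 1, 2 and 4 and arsenic replicate 4).

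In all, 10 of 57 tested lists passed the camera threshold, 3 higher and 7 lower, and 0 passed with an estimated correlation, where 2 lists had an unadjusted p under 0.05. With fry, which asks whether a list's genes move on balance one way, 0 passed and 8 had an unadjusted p under 0.05; with its test for change in either direction 10 passed, of which 6 were among those of camera. The splicing (adjusted p = 0.161), fibroblast (0.154), MHC class II (0.508) and B-cell lists (0.705) did not pass it, while the unfolded protein response, p53, aryl hydrocarbon receptor and negative clock lists did. With quantile normalization 7 lists passed camera, 1 higher and 6 lower, and the B-cell call also ended (adjusted p = 0.0546), as the matrix call did with median centring (0.0616). With the filter at the 75th percentile the calls of hypoxia genes (adjusted p = 0.0998), NRF2 targets (0.184), B cells (0.393) and matrix (0.0882) ended, and with array weights that of NRF2 targets (0.0688). Without a filter on dim probe sets 10 of 64 lists passed, but 7 higher and 3 lower, of which 6 were among the 10: the calls of fibroblast markers (adjusted p = 0.0635), MHC class II (0.0865), B cells (0.138) and matrix (0.478) ended, and heat-shock (0.0271), oxidative phosphorylation (0.00076), proteasome (0.000801) and selenoprotein genes (0.0258) passed, all higher. With the kidney level as a covariate 6 lists passed, 0 higher and 6 lower, and 4 of these were among the 10; besides MHC class II and glucocorticoid targets, the calls of hypoxia genes (mean 0.24 from 0.22, adjusted p = 0.0699), NRF2 targets (0.19 from 0.16, 0.0788), matrix (-0.087 from -0.068, 0.116) and B cells (-0.10 from -0.19, 0.316) ended. The B-cell call ended without control replicates 1 or 2 or arsenic replicates 1, 2 or 5 (adjusted p up to 0.412, mean -0.047 without control replicate 1), and the matrix call without control replicates 3 or 5 or arsenic replicates 1, 2 or 3 (up to 0.254, mean -0.034 without control replicate 3). The NRF2 call ended without control replicates 2 or 3 or arsenic replicates 2, 3 or 4 (up to 0.163), and the MHC class II call without replicate 2 of either group (up to 0.129); the mean of MHC class II was -0.097 without control replicate 2 and -0.35 without control replicate 4.

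None of the genes of this paragraph, which handle or answer to arsenic, passed the test over all genes. None of 7 metallothionein and metal-transport genes passed, also adjusted over the list alone. The metal-binding metallothioneins Mt1 and Mt2 were at 10.51 ± 0.41 and 10.47 ± 0.31 in controls and at 10.80 ± 0.34 and 10.89 ± 0.43 with arsenic (log2, n = 5 each); the log2 fold change of Mt1, 0.29, was 0.15 without control replicate 2 and 0.16 without arsenic replicate 3. The zinc transporters Slc39a14 and Slc39a10 had 0.24 and -0.10, the latter -0.052 and -0.17 without control replicates 4 and 5 and -0.0093 and -0.17 without arsenic replicates 2 and 4. None of 13 genes of arsenic metabolism and transport passed: the arsenic methyltransferase As3mt had 0.20 (SE 0.11; 0.13 without arsenic replicate 5), Ahcy 0.31, Pnp 0.25, Abcc4 0.31 and Gsto1 0.02. Heme oxygenase Hmox1 had 0.43 (SE 0.16, adjusted p = 0.25), Gclm 0.16, Gclc 0.01, Txnrd1 0.13 and Srxn1 0.23. A second probe set of Gclm had -0.15, and without control replicate 2 or arsenic replicates 3 or 5 Gclm had 0.094, 0.093 and 0.24. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, had the largest difference among them, from 7.58 ± 1.33 in controls to 9.27 ± 0.78 with arsenic (log2 fold change 1.69, SE 0.60, adjusted p = 0.237).

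None of 17 heat-shock genes passed. Hspa1a had 0.43 (SE 0.29; 0.20 without arsenic replicate 2 and 0.26 without control replicate 2), Stip1 0.35, Hspb8 0.27, Hspe1 0.19 and Ahsa1 0.21, while another probe set of Ahsa1 had -0.87. Of 17 p53 targets 1 rose, Cdkn1a, which the glucocorticoid list also holds. Plk2 had -0.75, Polk -0.46 and Mdm2 -0.28, of which Plk2 fell adjusted over the list alone. None of 15 inflammatory genes passed over all genes. The cyclooxygenase Ptgs2, at 8.81 ± 0.53 in controls and 7.45 ± 0.39 with arsenic, had an adjusted p of 0.0551 and fell adjusted over the list alone. Il1b had -0.94 (SE 0.38; -0.60 without control replicate 2), Il1r2 0.72 and Vcam1 -0.29.

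Genes of the circadian clock were fixed as 2 lists, which had mean differences of the same sign. Of 11 genes of the negative arm and its outputs (mean 0.19), 1 rose over all genes, the PAR-domain factor Tef (0.55, SE 0.09), and 3 adjusted over the list alone, with Per2 at 0.89 and Cry2 at 0.44. Tef passed in 2 of the 10 fits that left out 1 array, and its call ended without a filter on dim probe sets (limma adjusted p = 0.0513). A second probe set of Per2 had -0.49. Bhlhe40 had 0.39 (0.24 without arsenic replicate 2), Dbp -0.42 (SE 0.47), but 0.30 with the kidney level as a covariate, and Nr1d1 0.58 (SE 0.42). Without 1 array this list's mean ran from 0.10 (without control replicate 3) to 0.28 (without control replicate 1), Dbp from -0.74 to -0.088 and Nr1d1 from 0.29 to 0.84 (without the same animals). The other list, fixed as the positive arm, had a mean of 0.21 over 5 genes, but 2 of them, Cry1 (0.48) and Nfil3 (0.22), encode repressors. None of the 5 passed over all genes, and Cry1 alone rose adjusted over the list alone. The activators Arntl and Npas2 had 0.29 and 0.28, but Npas2 had 0.080 without arsenic replicate 3 and 0.16 without control replicate 1, and Nfil3 0.12 and 0.14 without arsenic replicate 2 and control replicate 4. The mean of the list without Cry1 and Nfil3, a choice made after seeing the data, was 0.13 (3 genes). With the kidney level as a covariate the negative arm had a mean of 0.36 and the full positive list 0.11. With array weights these means were 0.091 and 0.27.

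None of 15 type 2, 13 club, 15 alveolar macrophage or 20 endothelial markers passed the test. The surfactant gene Sftpc of alveolar type 2 cells was at 16.08 ± 0.08 and 16.03 ± 0.05, and the club-cell gene Scgb1a1 at 16.27 ± 0.05 and 16.26 ± 0.05, in control and arsenic lungs. The highest value of the whole table was that of Scgb1a1 in control replicate 5. Sftpc and Scgb1a1 thus lay near the top of the scale, where a difference may not show. Their near-equal values therefore say little about the content of these cells. With all 10 arrays none of these lists passed camera, with means of -0.052 (type 2, adjusted p = 0.118), -0.0075 (club, 0.324), 0.11 (macrophage, 0.552) and 0.054 (endothelial, 0.932). The type 2 list passed, lower with arsenic, without arsenic replicates 2 (mean -0.087, adjusted p = 0.0199) or 5 (-0.068, 0.0345) and with array weights (-0.062, 0.0462), and the club list without control replicate 2 (-0.32, 0.035) and without it and arsenic replicate 4 (-0.36, 0.0441), where the adjusted p of other refits reached 0.848 and 0.934. Transcripts of another organ were present as well. Kap, an androgen-regulated transcript of kidney tubules, and Umod, which encodes the urinary protein uromodulin, were at 2.26 and 3.45 in control replicate 1 and at up to 13.4 and 10.73 in arsenic replicate 4; both were named after their values were seen. The mean of 26 kidney transcripts was 4.68 ± 0.77 in controls and 5.64 ± 0.77 with arsenic (log2, n = 5 each; exact permutation p = 0.0952, two-sided).

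**Figure D3:**
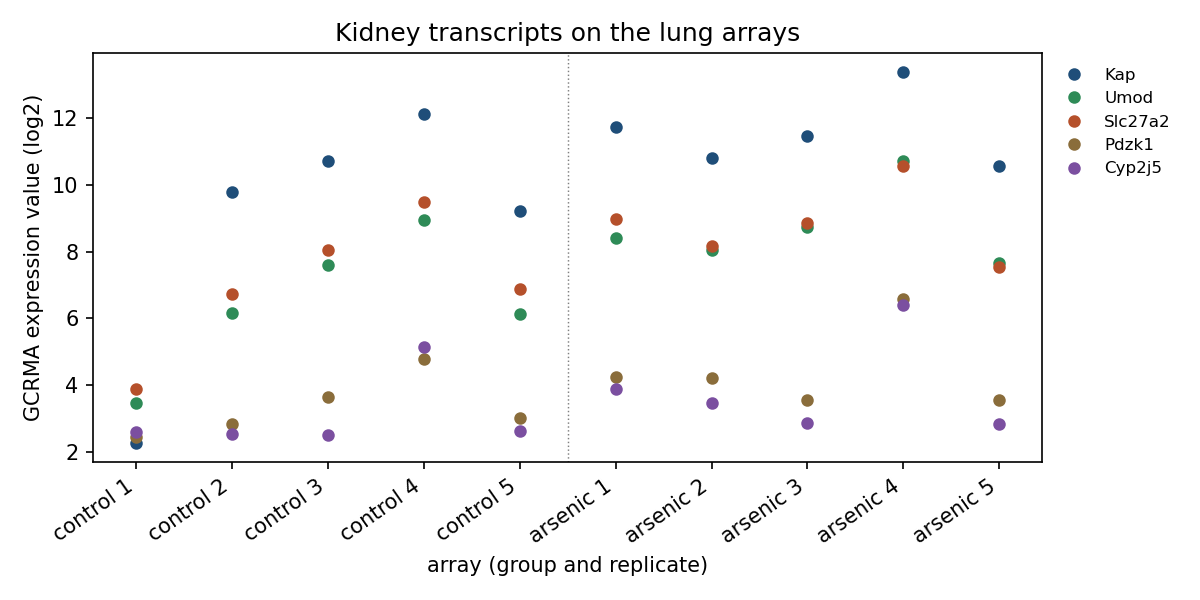
Expression value (log2, vertical axis) of 5 kidney transcripts on each of the 10 lung arrays (horizontal axis, group and replicate); each point is 1 array, and the dotted line parts control from arsenic. Kap lies at 2.26 in control replicate 1 and at 13.4 in arsenic replicate 4, and the other 4 transcripts are also highest in arsenic replicate 4.

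Along the first 3 principal components no difference between the groups passed the test with all 10 arrays. Component 1 held 35.8% of the variance and component 2 held 25.1%, and the group means differed with exact permutation p-values of 0.294 and 0.0873 (two-sided, n = 5 each; the smallest that 252 splits allow is 0.00794). Without control replicate 5, component 2 had an exact p of 0.0397. Component 3, along which kidney transcripts were seen, held 12.1% and had an exact permutation p of 0.0556. The 3' to 5' log2 ratio of the Actb control probe sets, a sign of RNA integrity, was 0.62 ± 0.04 in controls and 0.63 ± 0.08 with arsenic (exact permutation p = 0.754).

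The number of genes past the threshold changed when 1 animal was left out. It was 10, 31, 12, 17 and 24 without control replicates 1 to 5 and 41, 9, 27, 14 and 13 without arsenic replicates 1 to 5. It moved by over 1.5 times in each case but that of arsenic replicate 1. A fit with 1 array fewer can call fewer genes for that reason alone, which was not told apart from the share of the animal left out. In all 10 of these fits 9 genes passed, namely Nr4a1, Klf15, Adamts1, Zbtb16, Fkbp5, Map3k6, Fam107a and, named after their values were seen, Foxo3 and Ip6k2, while 10 of the 54 passed in none, among them Fst, Slc25a25, Rsrp1, Nipal1 and Eva1a. With the kidney level as a covariate, limma called 0 genes, with 2904 at an unadjusted p under 0.05. The log2 fold changes of the 54 genes kept a median ratio of 0.981, all 54 with the same sign and an unadjusted limma p under 0.05. Their standard errors grew by a median factor of 1.23.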

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

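The time of day at death, the kidney correlation over all 14 further genes, the joint score of glucocorticoid and immediate-early genes and the group difference of the kidney level were tested only after the values they rest on had been seen, and every covariate refit was chosen after seeing the data.

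7 of 232 groups of 5 animals held a value far from the other 4, where chance gives about 11.6, or 1 group in 20. The gap as a share of the group's range was 0.719 for Adm in arsenic replicate 1 (8.12 against 8.37 to 8.47), 0.732 for Spib in arsenic replicate 4 and 0.766 for Cry2 in arsenic replicate 1. It was 0.824 for Vcam1 in control replicate 1, 0.798 for Sftpc and 0.818 for Scgb1a1, both in arsenic replicate 3, and 0.723 for the mean of the metallothionein list in control replicate 2.

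The 54 genes between arsenic and control exceeded chance: 2 of 100 splits of the 10 arrays, the real one included, gave as many genes, and 96 of the other 99 gave none. The highest of the others called 1098. The 10 gene lists did not exceed chance, since 73 of the 100 splits gave as many, with 27 in the highest.

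The mean of the glucocorticoid targets lay higher and that of the immediate-early genes lower with arsenic. The difference between the means of both lists, joined because of their results, was 1.07 (95% interval 0.77 to 1.37). Taken singly, glucocorticoid targets had an unadjusted exact permutation p of 0.0159 and immediate-early genes of 0.00794, the smallest that the splits allow. After adjustment over the 57 lists each had an exact permutation p of 0.226. This adjustment can pass the threshold only if many lists lie at or near that smallest p, so it says little about either list. With the Actb 3' to 5' ratio as a covariate the difference of the lists was 1.03 (0.82 to 1.25). That ratio hardly differed between the groups (0.62 ± 0.04 and 0.63 ± 0.08, exact permutation p = 0.754), so this refit could change little. The near-equal ratios themselves argue against RNA degradation as the whole cause, as far as Actb shows it. With the kidney level as a covariate the difference of the lists was 0.90 (0.60 to 1.20), above 0.54, a bound taken from the difference without covariate. The rule for this bound was set before the refit, but after the results of both lists had been seen. With this covariate the single-gene calls nevertheless ended at a lowest limma adjusted p of 0.057, while log2 fold changes kept a median ratio of 0.981. The genes of that ratio had been called for their fit to the groups, so it says little about the kidney level. Standard errors grew by a median factor of 1.23 and the degrees of freedom fell from 10.8 to 9.83. Their shares in this, and that of the adjustment, were not told apart, as for Fkbp5 (1.76, SE 0.20, to 1.95, SE 0.24) and Nr4a1 (-2.54, SE 0.24, to -2.30, SE 0.27). A shift in the time of day at death stays open, since the positive minus the negative arm of the clock differed by 0.024 with a 95% interval from -0.50 to 0.55, and by -0.065 (-0.68 to 0.55) without the repressors Cry1 and Nfil3 in the positive list. A response to arsenic and a difference in handling or killing between the groups, which no label records, may both account for it and were not tested apart.

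Kidney transcripts varied widely between lung arrays, with Kap at 2.26 in control replicate 1 and at 9.21 to 13.4 on the other 9 arrays. Carry-over of kidney RNA or tissue is a candidate explanation: 14 kidney genes not looked at when the 12 others were chosen, 6 of them below the filter value on every array, had a median Spearman correlation of 0.764 with those 12, against 0.042 at the 95th percentile of 10000 random sets of like level, and of 0.675 against 0.117 without arsenic replicate 4. Their means correlated over the 10 arrays with Pearson's r of 0.856 (permutation p = 6e-04, adjusted 7e-04) and Spearman's rho of 0.952 (permutation p = 6e-05, adjusted 1e-04), and r was 0.90 without control replicate 1 and arsenic replicate 4; of 2 relations computed, the other used the 8 genes above the filter value on any array (r = 0.855). An effect of arsenic stays open, with 4.68 ± 0.77 in controls and 5.64 ± 0.77 with arsenic (n = 5 each; exact permutation p = 0.0952). Of the 54 genes called between the groups, 0 were among the 26 kidney genes. This says little about carry-over, since only 54 of 11333 genes tested were called. At least 6 of the 26 lay below the filter value on every array and could not be called.

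The split with 1098 genes, picked as the highest of the other splits drawn, set control replicates 1, 3 and 4 and arsenic replicates 1 and 4 against the other 5 arrays. It moved the splicing list, which lay lower with arsenic, by 0.36 (camera adjusted p = 3.47e-09, or adjusted p = 0.44 with an estimated correlation). Its lowest limma adjusted p was 0.0282, with 0 genes under 0.01, against 0.0050 and 9 genes between arsenic and control. A structure of the samples that crosses the exposure is a candidate explanation, but a split chosen for its count cannot establish it. The split shared 0 genes with the 54. Over 11333 genes, which are not independent replicates, its log2 differences correlated with those of arsenic at -0.585. The arrays it shares with the groups alone give -0.2, and 3 of the 77 drawn splits that share as many, itself included, went as far. Log2 differences of its genes kept a median ratio of 0.972 (quartiles 0.916 and 1.03) with the Actb ratio as a covariate. The median ratio was 1.01 (0.965 and 1.05) with the kidney level. These genes were picked for their close fit to the split, which leaves a covariate little to take up. The ratios therefore cannot decide whether either is a cause. With the Actb ratio the calls ended at a lowest adjusted p of 0.0712, with standard errors larger by a median factor of 1.12 and 3254 genes at an unadjusted p under 0.05, and with the kidney level 728 genes passed. A batch of RNA preparation or hybridisation, for which no label is used here, was not tested.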

How the results depend on the processing

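The kidney, Actb and other-split covariates, the removal of a pair of animals or of the control probe sets and the shorter clock list were chosen after seeing the data. The direction of every one of the 26 named genes past the threshold was kept in all 650 refits of them. For many of these refits this was fixed in advance. The groups of these genes do not overlap, so leaving out arrays cannot turn the sign. The t-test, the trended eBayes and the replicate block use the same fold change. In 381 refits the gene stayed past the threshold (for another probe set, an unadjusted p under 0.05), and in the other 269 it did not. Of 1691 refits of the 67 other named genes, 32 moved past the threshold and 25 changed sign. Without 1 array, the log2 fold change moved by over 1.5 times in 0 of the 26 and in 21 of the 67.

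The 54 genes became 108 at an adjusted p under 0.1, 99 with each probe set on its own (59 higher and 40 lower, against 43 and 11), 19 without a filter and 7 with the t-test. They became 5 with a replicate block. Over all genes, same-numbered animals did not deviate together (correlations -0.33 to 0.25, none of the 5 arsenic animals closest to its own number). With so few animals this cannot exclude a batch shared by number, so a pairing stays open. A cage shared across the groups is not at issue, since the groups had different drinking water. With covariates they became 0 (kidney), 140 (Actb) and 90 (the other split); without arsenic animal 4 and control animal 2 there were 11, and leaving out 1 array gave 9 to 41. Of the 54, 49 remained with quantile normalization, 49 with median centring, 41 with probe sets averaged, 18 without a filter and 54 without control probe sets. The 10 lists became 0 with an estimated correlation, 0 with fry and 6 with the kidney level, of which 4 were among the 10, and 9 to 14 without 1 array. Without a filter there were again 10, but 7 higher and 3 lower, with 6 shared. Without arsenic animal 4 and control animal 2 there were 9, 0 higher and 9 lower, with 5 shared. Of 26 refits each, the calls of the immediate-early, splicing and cholesterol lists held in 24, of fibroblast markers in 23, glucocorticoid targets in 22, hypoxia and MHC class II in 19, B cells in 12, extracellular matrix in 11 and NRF2 targets in 10. Component 2 had exact permutation p-values of 0.0397 to 0.825 without 1 array, the lowest without control replicate 5. The cause of these changes was not tested beyond what is said here.

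Gclc had -0.010 with quantile normalization, -0.040 with array weights, -0.058, -0.0090 and -0.16 with the kidney level, the Actb ratio and without the pair of animals, and -0.11 to 0.077 without 1 array. Gsto1 had -0.017 with array weights, -0.0050, -0.051 and -0.15 in those 3 added refits, and -0.21 to 0.21 without 1 array. Without 1 array, Scgb1a1 ran from -0.029 to 0.010 and the p53 list's mean from -0.0049 to 0.039. Dbp had -0.42, but 0.30 with the kidney level. The clock difference was -0.065 without Cry1 and Nfil3 in the positive list, against 0.024. Ahsa1 had -0.33 with probe sets averaged. A second probe set gave 0.083 for Loxl1, -0.87 for Ahsa1, -0.49 for Per2 and -0.15 for Gclm, the 4 of 43 named genes with another probe set where the sign differed; the cause was not tested. Dim probe sets near the array's floor limit what small folds can be seen.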

Other observations

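Genes of this part outside the rule for named genes were chosen after their values were seen. Of 24 genes of the unfolded protein response, none passed over all genes, but adjusted over the list alone 5 rose and 1 fell with arsenic. The proapoptotic factor Ddit3 had a log2 fold change of 0.50 (SE 0.11), Chac1, which breaks down glutathione, 0.84 (SE 0.18), Herpud1 0.41, the transcription factor Xbp1 0.25 and the secreted factor Manf 0.34, while Atf3, also an immediate-early gene, had -1.24 (SE 0.40). The list's camera adjusted p was 0.493 (adjusted p = 0.848 with an estimated correlation). Of 14 cytochrome P450 and related genes of the lung, 3 rose adjusted over the list alone: Cyp3a13 (0.62, SE 0.15), Cyp2d22 (0.42, SE 0.13) and Cyp2b10 (0.31, SE 0.07). The camera adjusted p of this list was 0.44, and again 0.848 with an estimated correlation. Of 6 measured genes of the aryl hydrocarbon receptor list, Cyp1a1 and Nqo1 rose and Ahr, the receptor itself, fell (-0.59, SE 0.14) adjusted over the list alone. Angptl4, a lipase inhibitor induced by fasting and by glucocorticoids, had 1.33 (SE 0.28) and rose adjusted over the fatty acid oxidation list alone.

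The widest spread between animals ran across the groups. Mucous-cell genes had the widest range of the 57 lists, 6.69 on the log2 scale, from arsenic replicate 5 to arsenic replicate 3 (group difference exact permutation p = 1, n = 5 each). Bpifa1, a secreted protein of the upper airways, lay at 8.22 in arsenic replicate 5, lower still in control replicate 2 and at 13.32 to 15.85 on the other 8 arrays. Adipoq, the adipocyte hormone adiponectin, was at 1.93 and 1.97 on the same pair of arrays and at 6.46 to 11.27 elsewhere, and the atrial peptide gene Nppa at 3.82 and 3.96, against 5.03 to 9.99. Neutrophil genes were highest in control replicate 2, where S100a8 was at 14.97 against 12.21 to 13.80 on the other arrays. Ighg3, an immunoglobulin heavy chain, was at 8.18 and 8.31 in arsenic replicates 1 and 5 and at 4.89 to 5.57 in the other 8 lungs.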
